A study of Mus musculus with 4 samples.

How the data were processed

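ChIP-seq was done on primary mouse cortical neurons whose chromatin was cross-linked with formaldehyde for 30 minutes and sonicated to about 150 bp, per the labels' protocols. Cytosine arabinoside at 2 µM was used against dividing cells. The labels name 4 libraries, 1 per group. The IgG and input libraries were not analysed here, so no background from them stands beside the peaks. Each peak list was tied to its library by the hairpin its name gives.

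The genome build was mm10 and MACS2, deepTools and MultiQC were used, per the submitters' processing notes. Aligner, control library of the calls, thresholds, duplicate filtering and sequencing depth are not given in the sources used here. Each condition has a single library, so no calls could be pooled over replicates. For each peak the deposited lists give position, rank, a p-value score, a fold enrichment over the caller's background (a ratio), a length, a summit and a tag number, all the authors' values. Starts and ends are as deposited and were read as 1-based, because in most peaks the length equals end minus start plus 1; this is an inference from the values.

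The deposited score comes in 2 forms. In 84 control and 886 knock-down peaks the length matches the interval and the score is at least 50.03, as early MACS releases write a p-value. In 9 control and 66 knock-down peaks the length is shorter than the interval and the score runs from 6.08 to 16.2, apart from a single 104.9, as MACS2 writes one. In 8 knock-down peaks of the second form the tags are not whole numbers. How the forms came to be joined is not given in the sources used here. Peaks were ranked in the deposited order, which mixes both scales and places most second-form peaks low, so rankings by score carry that limit.

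Gene positions came from a RefSeq table of GRCm38.p6, whose chromosomes have the coordinates of mm10. It gives neither strand nor exons. The planned distance to a transcription start site was therefore replaced by the distance from the summit to the nearer of both gene ends, over 34328 coding and lncRNA genes for positions and 21631 coding genes for gene lists. This can count a peak at the 3' end of a gene. The planned classes of exon, intron and untranslated region were reduced to near a gene end, inside a gene and between genes. The planned ATF4 motif search was not run, as no genome sequence was used here.

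Overlaps of at least 1 bp were found with bedtools 2.31.1. Chance overlap came from 1000 random placements of each kind, and the chance share near gene ends from 200. Gene lists were tested with a one-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 18 lists in 2 peak lists with a threshold of 0.05. All 378 list members matched a gene symbol or an older one. Shares have exact Clopper-Pearson intervals and tags exact Poisson intervals at 95%. They cover counting error only, and tags are not scaled for depth. Alternatives covered a stricter score, a fold minimum, the overlap rule, merging of near peaks, the window and gene set, the first score form alone and equal list lengths. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

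The gene lists, tests and rule for named genes were fixed before the data were examined, apart from the changes stated. The rule took list members with a peak within 5 kb in either list, up to 30 by knock-down score, the 10 highest-scoring peaks of each list, up to 5 unshared control peaks by score, and Opa1 and Atf4. Pck2, Bdnf, Slc7a5 and Aars and the genes named in the closing part outside this rule were chosen after their values were seen. The steps were tested on simulated lists for the comparison of control and knock-down peaks. All 80 planted shared peaks were recovered with 0 others, and among 21631 coding genes 3 of 3 lists with 6 planted bound members each were called, with 0 of 15 others. The planted peaks were placed so as to overlap and the planted lists lay far above chance. The simulation therefore checked the code and not its sensitivity to smaller signals.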

Results

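Binding of the transcription factor ATF4 to chromatin was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary mouse cortical neurons. ATF4 is the main transcriptional effector of the integrated stress response, which adjusts amino acid supply and protein synthesis under stress. Neurons from embryos of CD1 mice, an outbred stock, were transduced on day 6 of culture with lentivirus and harvested on day 11. The libraries were labelled by a control short hairpin RNA or one against Opa1, a GTPase of the inner mitochondrial membrane needed for its fusion. The series held 4 libraries, 1 in each group: ATF4 ChIP from control neurons, ATF4 ChIP from Opa1 knock-down neurons, and IgG ChIP and input DNA from control neurons. The values analysed were the authors' peak lists of the 2 ATF4 libraries. With 1 library per condition, differences between conditions have no replicate check and were not tested, and the intervals given cover counting error only. Total read numbers were not given in the sources used here. Tags inside peaks summed to 2424 over 40.8 kb in the control list and 33318 over 572 kb in the knock-down list. A peak's fold enrichment, score and tag number are the authors' own values and describe that peak within its list.

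The first comparison asked how many sites ATF4 occupied with and without Opa1 knock-down. The control list held 93 peaks and the knock-down list 952, or 10.2 times as many. A fold enrichment over the caller's background of at least 10 was reached by 20 control peaks and 285 knock-down peaks, and one of at least 20 by 0 and 34. The median fold was 7.53 in the control list (maximum 16.9) and 8.13 in the knock-down list (maximum 52.1). Median peak width was 444 bp and 590 bp. Peak number depends on sequencing depth and calling threshold, neither of which was given.

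**Figure D1:**
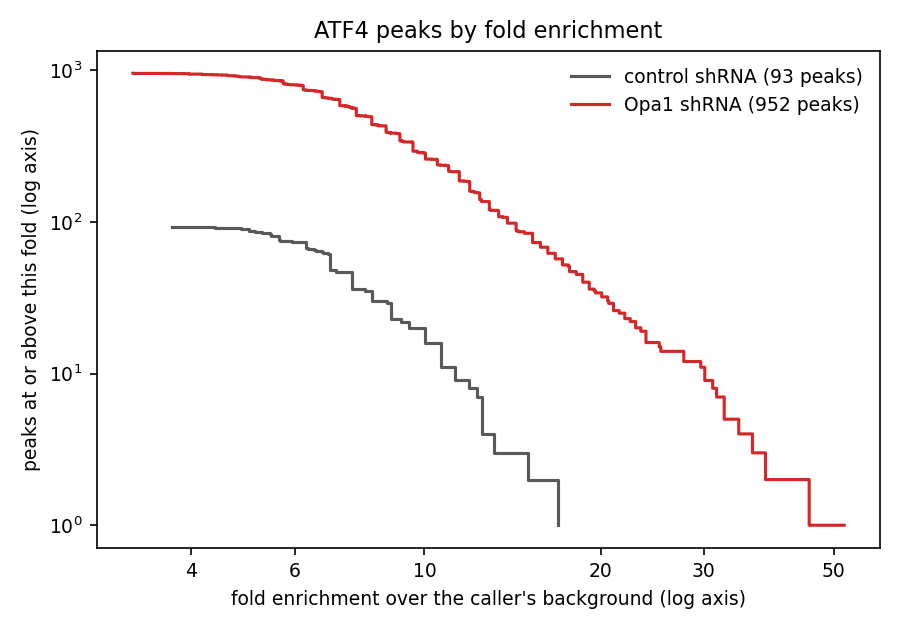
Number of ATF4 peaks (y axis, log scale) at or above each fold enrichment over the caller's background (x axis, log scale) in the control list (grey line, 93 peaks) and the Opa1 knock-down list (red line, 952 peaks), 1 library each. At a fold of 10 the lists hold 20 and 285 peaks.

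The second comparison asked whether sites bound in control neurons were found again after Opa1 knock-down. Of the 93 control peaks, 80 overlapped a knock-down peak by at least 1 bp (86.0%, 95% Clopper-Pearson interval 77.3 to 92.3), and 872 knock-down peaks overlapped no control peak. Among the 93 highest-scoring knock-down peaks, 53 were shared. Random placement of the control peaks on their chromosomes gave a mean of 0.040 overlaps and at most 1 in 1000 placements. Placement at the same distance from a random gene end gave a mean of 0.082 and at most 2. Both lists may share control libraries in their calling, which random placement leaves out. The series held no IgG or input library from knock-down neurons, so the knock-down calls had no matched background from it.

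The 10 highest-scoring control peaks included sites beside Chac1, an enzyme that degrades glutathione, and near Atf5, a stress-responsive transcription factor, and a site in Sars, the cytosolic seryl-tRNA synthetase. The others lay inside Tmx3, Auts2, Atrnl1 and Magi2, or had Gm42048, Creb3l1 (31554 bp away) or Lcorl (17924 bp away) as the nearest coding gene. The 10 highest-scoring knock-down peaks also held the Tmx3, Gm42048, Chac1, Auts2, Atrnl1 and Atf5 sites. The remaining 4 lay inside Slc3a2, the heavy chain of several amino acid transporters, beside Herpud1 and Ddit3, and 38308 bp from Arntl, a core clock gene. All 10 overlapped a control peak. The first of them, at chr8 121850688 to 121851677 (mm10), had a fold of 52.1 and 214 tags (95% Poisson interval 186 to 245). It lay inside an annotated non-coding gene, 7281 bp from Gm42048 and 29963 bp from Slc7a5, the light chain of a large neutral amino acid transporter.

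The 13 control peaks with no knock-down partner had a median fold of 5.65, against 7.53 for the 80 shared control peaks. The 5 with the highest score had Prl2c3 (fold 6.47), Pla1a (8.62), Fzd8 (5.65), Fam162a (5.02) and Rfpl4b (6.27) as the nearest coding gene. The Fam162a peak lay inside that gene, 11777 bp from its nearer end, and the Pla1a peak lay outside its gene, 1547 bp from the nearer end.

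The third comparison asked where the peaks lay relative to genes. In the control list 24 of 93 summits were within 1 kb of an annotated gene end (25.8%, 95% Clopper-Pearson interval 17.3 to 35.9), 35 peaks were elsewhere inside a gene and 34 between genes. In the knock-down list 145 of 952 were within 1 kb (15.2%, 13.0 to 17.7), 450 elsewhere inside a gene and 357 between genes. Random placement of knock-down peaks put a mean of 4.88% within 1 kb. A pair of tests within the knock-down list was chosen after the data were seen. The 93 highest-scoring peaks were near a gene end in 27 cases and the other 859 in 118 (two-sided Fisher's exact test, odds ratio 2.57, p = 0.00036). Peaks shared with the control list were near a gene end in 25 of 80 cases and the rest in 120 of 872 (two-sided Fisher's exact test, odds ratio 2.85, p = 0.00013). These groups overlap, so the tests are not independent. Strand and exons were not used here, so gene starts and ends, and exons, introns and untranslated regions, were not told apart.

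The fourth comparison asked which gene groups carried ATF4 peaks within 5 kb of a gene end. Regulators of the integrated stress response had 7 of 19 members bound in the control list and 15 of 19 in the knock-down list. That group is named for its regulators but also takes in other genes of the response, such as the enzyme gene Chac1. Genes of amino acid synthesis and one-carbon metabolism had 4 and 10 of 17. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 4 and 9 of 20, and amino acid transporters 0 and 4 of 13. Across the 18 lists, 16 of 378 genes had a peak in the control list and 46 in the knock-down list, and all 16 were among the 46.

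Enrichment was tested within each list against 21631 coding genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted over 36 tests). In the control list, where 48 coding genes were bound, the adjusted p was 9.9e-14 for stress response regulators, 3.6e-07 for amino acid synthesis and 6.0e-07 for cytosolic synthetases. In the knock-down list, with 268 bound genes, the same groups had adjusted p of 2.2e-24, 2.3e-14 and 8.1e-12, and transporters 7.8e-05. These tests do not compare the conditions, and the groups were compiled from general knowledge that includes known ATF4 targets. In the higher-scoring part of the control list, 1 synthetase was left within the 5 kb window and that group missed the threshold (adjusted p = 0.14, Fisher's exact test). In the 93 highest-scoring knock-down peaks, a setting chosen after the data were seen, 1 transporter was left and that group missed it (adjusted p = 0.13, Fisher's exact test).

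Chac1, Atf5, Herpud1, Ddit3, Cebpg, Cebpb and Ddit4 were the members of the stress response group with a peak in both lists. The Chac1 peak had a fold of 15.1 and 47 tags (95% Poisson interval 34.5 to 62.5) in the control list, and 45.4 and 179 tags (154 to 207) in the knock-down list. The peak beside Ddit3, which encodes the pro-apoptotic factor CHOP, had folds of 10.04 and 34.4. Its summit in the control list was 267 bp from Ddit3 and inside the gene Mbd6. The peak beside Herpud1, of endoplasmic reticulum-associated degradation, had folds of 12.5 and 32.5. The Atf5 knock-down peak was 2463 bp from Atf5 and inside the overlapping genes Nup62 and Il4i1b. Eif4ebp1, a repressor of cap-dependent translation, had a peak in the knock-down list alone (fold 17.2), as did Trib3 (15.3), Sesn2 (14.3), Vldlr (12.4) and Gdf15 (10.01). Neither Atf4 nor Opa1 had a peak within 5 kb in either list. The ChIP data do not measure Opa1 expression, so the knock-down itself was not checked.

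In amino acid synthesis, Shmt2, Asns, Gpt2 and Pck2 had a peak in both lists. Asns, the asparagine synthetase gene, had folds of 10.04 and 17.7, and Shmt2, the mitochondrial serine hydroxymethyltransferase, 11.9 and 20.1. Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, had folds of 8.15 and 7.65, and was the 1 of the 16 list genes bound in both lists whose value was not higher in the knock-down list. The Shmt2 peaks also counted for the neighbouring Ndufa4l2. A further shared peak, inside Ndufa4l2 (folds 7.53 in the control and 12.9 in the knock-down list), counted for both genes too. Psat1, of serine synthesis, had a knock-down peak at chr19 15924871 to 15925528 (mm10), with its summit 141 bp from a gene end and a fold of 17.2. Got1 (13.9), Pycr1 (11.95) and Aldh1l2 (11.5) also had a peak in the knock-down list alone. Among synthetases, Sars, Cars, Yars and Iars had a peak within 5 kb in both lists. Eprs (15.3) and Mars1 (12.9) were among those in the knock-down list alone. A peak inside the synthetase gene Aars was also in both lists but lay outside that window. Its folds were 12.5 in the control list, where it ranked 14, and 30.1 in the knock-down list. The bound transporters included Slc7a1, a cationic amino acid transporter (fold 9.14), and Slc1a4, a neutral amino acid transporter (11.95). Outside the 5 kb window, a further peak with Slc7a1 as its nearest coding gene was in both lists. It lay 19377 bp away in the control list, with folds of 6.9 (control) and 25.3 (knock-down). With peaks inside genes counted too, a setting chosen after the data were seen, 2 transporters were bound in the control list and 8 in the knock-down list (one-sided Fisher's exact test, adjusted p = 0.0036 and 2.1e-09). Under that setting cytosolic synthetases had 5 and 10 bound genes, amino acid synthesis 4 and 12, and stress response regulators 7 and 15.

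The other 14 groups did not pass the test in either list. Hspa9, the mitochondrial HSP70, was the 1 bound gene of 13 mitochondrial chaperones and proteases (knock-down list, fold 19.5, adjusted p = 0.49, Fisher's exact test). Hspa5, the endoplasmic reticulum HSP70, was the 1 of 12 endoplasmic reticulum chaperones (fold 11.5), and Bdnf, named after its value was seen, the 1 of 9 immediate early genes (7.17). Nuclear-encoded respiratory chain subunits had 1 and 3 of 87 bound in the control and knock-down lists, and cytosolic ribosomal proteins 0 and 2 of 80. No peak in either list lay within 5 kb of the 17 mitochondrial aminoacyl-tRNA synthetases, 9 mitochondrial dynamics genes, 14 autophagy genes, 10 antioxidant genes, 20 synaptic genes or 14 neuron markers. The same held for 9 astrocyte, 8 oligodendrocyte lineage and 7 microglia markers. For these groups 0.016 to 0.25 bound genes were expected by chance, so a small enrichment was not detectable.

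**Figure D2:**
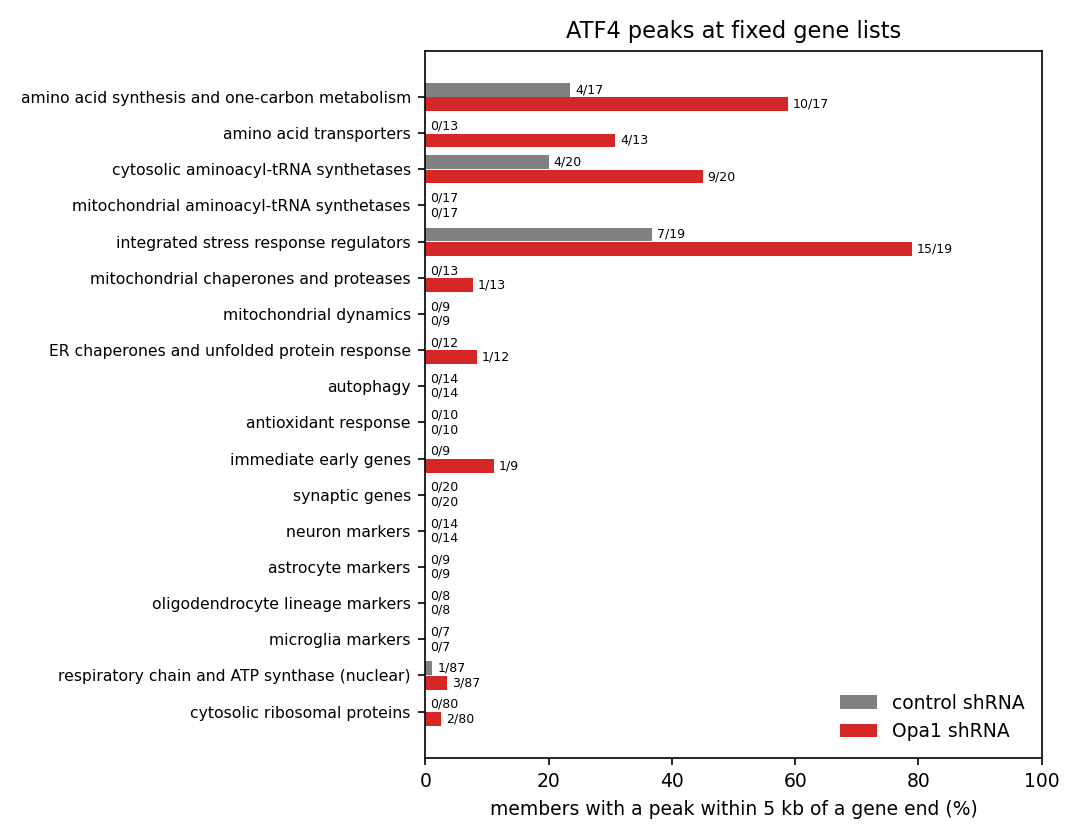
Share of the members of each of the 18 gene lists (x axis, percent) with an ATF4 peak within 5 kb of a gene end in the control list (grey bars) and the Opa1 knock-down list (red bars), 1 library each, with bound over all members beside each bar. Stress response regulators reach 7 of 19 and 15 of 19, and 9 lists are at 0 in both.

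The last comparison asked how peaks were spread over chromosomes. Knock-down peaks lay on every autosome, at 0.86 to 1.41 times the number expected from annotated length. The X chromosome carried 9 of them (0.95%, 95% Clopper-Pearson interval 0.43 to 1.79) where 62.2 were expected, and 0 of the 93 control peaks (0 to 3.89) where 6.08 were expected. Within 10 kb of another peak of the same list lay 2 control peaks (2.15%) and 29 knock-down peaks (3.05%).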

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

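Chosen after the data were seen were the fold minimum, the first score form alone, the rescaled second-form scores, the gene interior, length-matched random lists, equal list lengths for gene lists, and every setting of the fold ratio at shared peaks. Peak numbers were 46 and 476 in the higher-scoring parts of the control and knock-down lists by construction, and 20 and 285 at a fold of at least 10. The 80 shared peaks became 43 in the higher-scoring parts, 39 there with second-form scores multiplied by 10, and 53 against as many top knock-down peaks as control peaks, all with fewer peaks entered. The share near a gene end was 47.3% in the control list and 31.2% in the knock-down list with the wider window of 5 kb. In the knock-down list it was 11.2% with coding genes alone, where fewer gene ends count, 18.5% in the higher-scoring part and 29.0% in the top 93; the cause of these last changes was not tested. The other 43 values for the main results, fold ratio included, were classed as not moved. They include 66 shared peaks in place of 80 when a reciprocal overlap of 50% was asked for. As a share of the 93 control peaks, 66 lies below the 95% interval of 77.3 to 92.3 given above. They also include 886 knock-down peaks in place of 952 with the first score form alone. Stress response regulators and amino acid synthesis passed the threshold under all 10 alternatives in both lists, with the adjusted p at most 0.00051 and 0.0015 (Fisher's exact and random-list permutation tests). Some of these settings could not change the outcome. Restriction to autosomes and the X chromosome removed no peak from either list. Merging left all 93 control peaks, and equal list lengths left the control list as it was. The value of 0.00051 is set by the floor of 10000 random lists. Cytosolic synthetases in the control list passed under 9 of 10 (adjusted p 3.0e-08 to 0.14) and transporters in the knock-down list under 9 of 10 (2.1e-09 to 0.13, the highest with the top 93 peaks). Transporters in the control list passed under the nearest-gene rule (adjusted p = 9.6e-05) and with gene interiors (0.0036), by Fisher's exact test. No paired analysis was possible because each condition has 1 library. All motif alternatives were not run for want of a genome sequence. Depth is unknown, so a site missing from the control list is not shown to be unbound.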

Other observations

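Apart from the comparison of peaks near list genes with other shared peaks, all tests here were chosen after the result was seen. Ppp1r15b, a regulatory subunit of the phosphatase that acts on eIF2 alpha, had a peak 50 bp from a gene end in the knock-down list, with a fold of 22.0 and 86 tags, and it overlapped a control peak. Among 47 translation initiation factor genes, Eif1, Eif3c, Eif2s2 and Eif5 had a peak within 5 kb in the knock-down list and Eif1 and Eif3c in the control list. At least 4 bound genes came up in 0.19% of 10000 random lists matched on gene length. The family was picked because bound members had been seen, so this share is a description and not a test of chance. App, the amyloid precursor protein gene, held 2 knock-down peaks far inside the gene, 64772 and 99873 bp from an end, with folds of 16.7 and 13.9, and neither overlapped a control peak.

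The 227 coding genes of at least 500 kb held 97 knock-down peaks, or 10.2% (95% Clopper-Pearson interval 8.34 to 12.3), and 7 control peaks, or 7.53%. Random placement of the knock-down peaks gave a mean of 7.26%, a central 95% range of 5.57 to 9.03 and a highest value of 10.4 in 1000. Cntn4, Dlg2, Nrg3, Pde4d and Tenm4 held 3 knock-down peaks each.

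At the 80 shared sites the authors' fold was higher in the knock-down list at 75 and lower at 5, with a median ratio of knock-down to control fold of 2.26 (95% bootstrap interval over peaks 2.10 to 2.36). These folds come from separate calls with unknown settings and control libraries, so the ratio is a description of the lists and not a measured change in binding. If the calls were otherwise alike, deeper sequencing alone would leave this ratio near 1, and 2.26 would argue against it as the whole cause. That likeness is not shown, and the window of the first-form calls is not known. The commonest second-form length was 149 bp in the control list and 192 bp in the knock-down list. Background was inferred from the fold steps of first-form peaks and divided by these second-form lengths, which mixes both forms. It came to 10.7 and 10.9 tags per kb. A higher immunoprecipitation yield in the knock-down library could give a common gain, and in the higher-scoring part of the control list peaks near list genes (10) and others (35) did not differ detectably (two-sided permutation test, p = 0.38), which does not show equality. Yield therefore cannot be told apart from an effect of the Opa1 hairpin on ATF4 binding, which stays open and untested with 1 library per condition.

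The X chromosome held 9 knock-down peaks (95% Poisson interval 4.12 to 17.1) against 65.9 expected from its length at the autosomal rate. Its share of coding genes would give 44.1 peaks, above that interval. With peak tags lowered as for a single X copy in every cell, 11.9 peaks would be left at a tag threshold of 22, inside the interval. The list itself holds peaks below that threshold (minimum 13.7 tags), so the rule drops peaks even at full copy number and may overstate the loss. A lower number of X copies open to binding is therefore a candidate that these values cannot decide. Tags at 0.75 of the autosomal level, as if embryos of both sexes were equally frequent and both female copies equally bound, would leave 32.5, but inactivation of a female copy would bring such a mixture near the single-copy setting, so mixed sexes are not excluded. The sex of the embryos is not given, these values rest on a simple tag threshold of 22, and mappability and a lower density of ATF4 sites on X were not tested.

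A peak near Cwc22, at chr2 77950775 to 77952310 (mm10) in the knock-down list, had 168 tags but a fold of 9.51, and its control counterpart 54 tags and a fold of 3.71. Its tags per unit of fold, 17.7 and 14.6, were the highest of each list, where the next highest were 9.44 and 5.16. A raised local background, such as extra copies of the region in the outbred CD1 stock relative to the reference, is a candidate explanation that the test could not decide. The test asked for a place above the 99th percentile of both lists, and the highest of 93 control peaks can exceed only 98.9% of them. Both are second-form peaks, ranked 283 in the knock-down list and 85 in the control list as deposited. With second-form scores multiplied by 10 they would rank 4 and 8, so both would enter the 10 highest-scoring peaks. Copy number itself was not measured, and no biological explanation was tested.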
